A study of Mus musculus with 30 samples.

How the data were processed

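The series holds 30 mouse samples, of which 4 RNA libraries of 8-cell embryos have a column in the table used here, 2 after control knockdown and 2 after knockdown of Yy1 with the siRNA the labels number 1. Groups and replicate numbers come from the sample titles. The other 26 samples were not analysed here. Libraries were made from total RNA with a stranded SMART-Seq kit, per the labels' protocols. The table's values are FPKM as deposited by the authors, with 49585 rows and 49492 distinct symbols, 93 of which stand on more than 1 row. The submitters' processing notes name Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts, SAMtools 1.4.1, R 4.0.3, Bowtie2 2.4.3 and bedtools, with the mm10 build, without assigning them to assays. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Gene copies, overlapping genes and antisense partners are therefore uncertain, and Gapdh, a gene that most cells use, was listed at 0.148 to 0.33 FPKM. Of the symbols, 47240 matched a gene ID, and biotypes and coordinates come from the RefSeq table of GRCm38.p6, the assembly behind mm10.

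FPKM keep the depth where whole fragments were counted, so fragment totals and counts were recovered from the steps between values. Of 12120 genes above the filter, 12119 gave whole counts in all 4 libraries within 0.02 fragments. On simulated libraries 4 of 4 totals and 95.4% of 762 genes came out exactly; the rest can be understated by a common factor. The recovered totals were 34429515 and 31405476 fragments for control replicates 1 and 2, and 34074291 and 29302489 for Yy1 knockdown replicates 1 and 2. PCR copies are not independent molecules, so depth limits counting error only.

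Genes with a mean of at least 1 FPKM over the 4 libraries were tested on log2(FPKM + 1), with the values as deposited and no further scaling. limma 3.58.1 in R 4.3.3 fitted a model with group alone and moderated the spread with a mean-variance trend, and p was adjusted after Benjamini-Hochberg with a threshold of 0.05. A fold change on this scale understates the change of low genes. The 27 gene lists, the tests and the rule for named genes were fixed at the same stage as the alternatives below. Lists with at least 3 measured members, 23 of them, were tested with camera and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The list of YY1 and its family had 2 measured members, Yy1 and Zfp42. The named genes are Yy1, the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with at least 5 FPKM in the higher group and both knockdown libraries on the same side of both controls, and up to 4 members per list by smallest p. Predicted and clone names were counted, not named. Where too few passed, places were filled by the smallest unadjusted p, which is how all places were filled here; Yy1 holds a place among the 10.

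The labels do not say whether replicates come from separate collections of embryos. The limma p-values of single genes therefore measure the spread between these libraries, which may be technical. With its preset correlation, camera sets a list against the scatter of all genes, so these p-values hardly measure the spread between libraries. With an estimated correlation, camera uses the 2 residual degrees of freedom between libraries. Counts of replicate libraries differed far beyond sampling noise (chi-square per degree of freedom 75.7 in control and 50.7 in Yy1 knockdown). Pearson correlations were 0.969 between control replicates and 0.966 between Yy1 knockdown replicates. Across groups they were 0.959 to 0.97, so replicates were hardly more alike than libraries of different groups. The fit was tested on 10 simulated tables of 12120 genes for this comparison, each with 200 changed genes. These 200 were drawn only from genes with a mean above about 5 FPKM, so the shares called do not hold for lower genes. On the log2 scale limma called 96.6% of the genes changed by 3 and 14.1% of those changed by 1. It made 7.1 false calls per table, and camera called a list shifted by -0.3 in 10 of 10 tables. The share of genes called depends on how many are changed, so it cannot tell how many such changes the data hold. In the data, Yy1 at -3.26 (limma adjusted p = 0.0556) and Platr16 at 2.93 (0.205) were not called, though the mean of Platr16 was below 5 FPKM. Simulated noise was independent between genes, so the list result holds for uncorrelated genes only. The shift of -0.3 also exceeded the mean of the oxidative phosphorylation list, -0.204. Alternatives chosen before the data were examined were another pseudocount (0.1), no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, a replicate block, leaving out each library, other moderation and thresholds, and camera with an estimated correlation, on ranks, and fry. Protein-coding genes alone (8216 whose symbol has that RefSeq biotype; 1474 tested rows have no match, among them the histone and mitochondrially encoded genes) and limma-voom on recovered fragments were added after the data were seen. Python 3.11.15 and matplotlib 3.10.9 drew the figures.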

Results

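RNA was sequenced from 8-cell mouse embryos after knockdown of Yy1, the gene of the zinc finger transcription factor YY1, with 1 siRNA, and after a control knockdown. Each group held 2 libraries. The series title names nucleosome remodeling mediated by YY1, and this comparison asks which transcripts differ at the 8-cell stage when Yy1 is knocked down. The remaining 26 of the 30 samples (MNase-seq of zygotes, 2-cell and 8-cell embryos and embryonic stem cells, and CUT&RUN for YY1) were not analysed here. The deposited values were FPKM, fragments scaled to gene length and to the library's total. The steps between low values gave the depth behind them, 34429515 and 31405476 fragments for the control libraries and 34074291 and 29302489 for the Yy1 knockdown libraries. Between 23329 and 24755 genes were above 0 in a library.

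Yy1 itself, on chromosome 12 from 108792945 to 108820148 of mm10, stood at 77.7 and 71.2 FPKM in the control libraries and at 5.89 and 7.98 FPKM in the Yy1 knockdown libraries. Its mean was 74.5 ± 4.56 FPKM (SD, n = 2) after control knockdown and 6.94 ± 1.48 FPKM (SD, n = 2) after Yy1 knockdown, a 10.7-fold lower level. The log2 fold change was -3.26 with a standard error of 0.19 and a limma adjusted p of 0.0556, just short of the threshold of 0.05. Yy2, a relative of Yy1, was listed at 0 in all 4 libraries.

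By unadjusted p, Yy1 was followed by the predicted gene Gm13230, outside the naming rule and named after its values were seen, with 4.71 ± 1.55 FPKM in control and 43.2 ± 1.18 FPKM in Yy1 knockdown libraries (SD, n = 2 each), 9.16-fold higher with a limma adjusted p of 0.0928. Zfp42 and Baz1a came next, both lower. Zfp42, which encodes the pluripotency-associated zinc finger protein REX1, a relative of YY1, had 30.4 ± 0.318 FPKM in control and 4.71 ± 1.02 FPKM in Yy1 knockdown libraries (SD, n = 2 each), 6.46-fold lower. Baz1a, whose product ACF1 is a subunit of ISWI-type nucleosome remodelers, had 122 ± 0.685 and 30.7 ± 6.61 FPKM (SD, n = 2 each), 3.97-fold lower. Zfp42 lies on chromosome 8 from 43295067 to 43307009, and Baz1a on chromosome 12 from 54892989 to 55014371. Their limma adjusted p was 0.0928 and 0.183. Over 12120 genes with a mean of at least 1 FPKM, limma called 0 genes at an adjusted p of 0.05, while 1079 genes had an unadjusted p under 0.05 (511 higher and 568 lower), against 606 that chance alone would give. With 2 alternatives added after the values were seen, limma called 14 of 8216 genes tested alone whose symbol RefSeq lists as protein coding, and limma-voom on recovered fragments called 13 genes. Yy1, Zfp42, Baz1a and 6 others were among the 9 genes that both of these called. Uqcc2, Ndufa5, Ndufs4 and Ndufaf6 were called with protein-coding genes alone and not with voom. Of these Uqcc2, Ndufa5 and Ndufs4 had limma-voom adjusted p values of 0.109, 0.0838 and 0.109.

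The other genes that the naming rule took on the lower side did not pass the threshold over all genes either. Thrap3, a splicing and transcription cofactor, had a mean of 16.05 FPKM in control and 3.49 FPKM in Yy1 knockdown libraries. Ndufa5 and Ndufs4, subunits of respiratory complex I, had 14.02 and 9.6 FPKM in control against 2.73 and 2.85 FPKM. Uqcc2, an assembly factor of respiratory complex III, had 14.3 against 3.36 FPKM. Kif5b, a kinesin heavy chain, had 39.6 against 16.4 FPKM. Srp68, a subunit of the signal recognition particle, had 18.96 against 7.06 FPKM, and Ccng1, which encodes cyclin G1 and is a target of p53, had 10.9 against 2.67 FPKM. Their limma adjusted p was 0.237 each.

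On the higher side, Hk2, which encodes the glycolytic enzyme hexokinase 2 on chromosome 6 from 82725025 to 82774454, had 5.17 ± 0.179 FPKM in control and 14.03 ± 0.114 FPKM in Yy1 knockdown libraries (SD, n = 2 each), a limma adjusted p of 0.237. The noncoding transcript Platr16 had 0.524 and 0.0958 FPKM in the control libraries and 10.6 and 7.34 FPKM in the Yy1 knockdown libraries, with 2 to 240 fragments per library. Rhox9, an X-linked homeobox gene, had 1.61 against 6.06 FPKM. Hist1h2aa, a histone H2A gene, had 138.5 against 223.8 FPKM. Spink2, a protease inhibitor gene, had 4.29 against 10.8 FPKM. Cbfb, which encodes the shared subunit of core binding factor, had 6.69 against 14.4 FPKM. S100a10 had 3.24 against 7.41 FPKM, Mios, a component of the GATOR2 complex, 3.85 against 7.99 FPKM, and Teddm1b 2.81 against 7.12 FPKM. Mir680-2 had 1.37 against 8.26 FPKM from 4 to 41 fragments. The limma adjusted p of these genes lay between 0.205 for Platr16 and 0.462 for Mios.

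**Figure D1:**
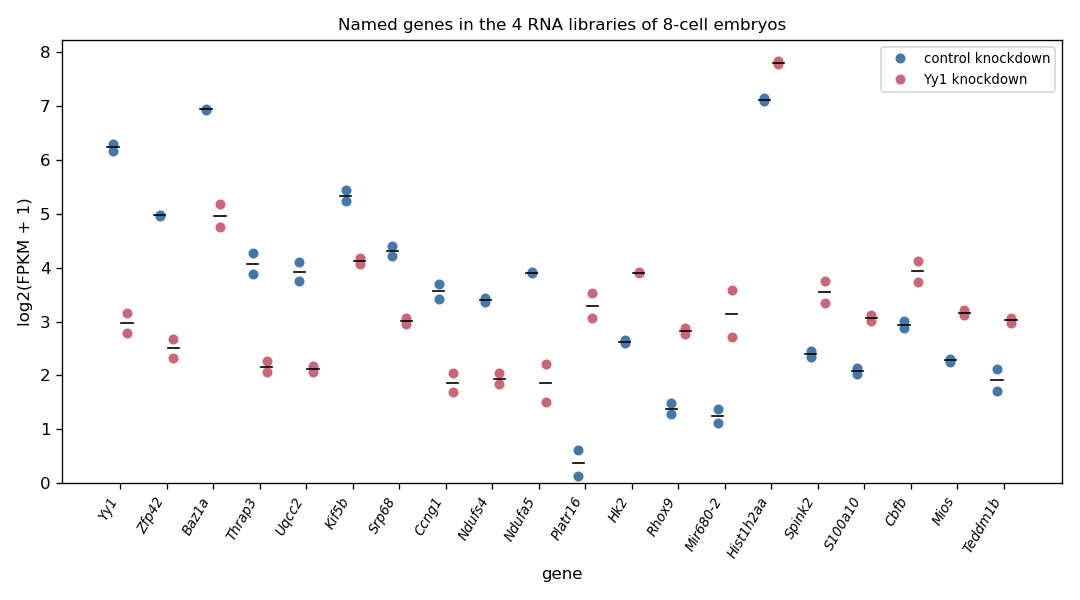
Levels of the 20 named genes, as log2(FPKM + 1), in the 2 control knockdown libraries (blue) and the 2 Yy1 knockdown libraries (red) of 8-cell embryos; each point is a library and each short line the mean of a group. Yy1 stands at 77.7 and 71.2 FPKM in the control libraries and at 5.89 and 7.98 FPKM after its knockdown.

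Transcripts of the nuclear genes for oxidative phosphorylation subunits fell as a list. Of 77 measured members 52 were lower and 25 higher, with a median log2 fold change of -0.12 (camera adjusted p = 0.00069, adjusted p = 0.773 with an estimated correlation). The estimated correlation of this list, -0.00599, was below the preset 0.01. This argues against correlation between genes as the reason the call was lost in that setting. None of the 77 passed over all genes tested with limma (16 lower and 1 higher had an unadjusted p under 0.05), and 9, all of them lower, passed adjusted over the list alone. Besides Ndufa5 and Ndufs4 these included Ndufa3, at 8.59 against 3.08 FPKM, and Ndufc1, at 21.8 against 12.1 FPKM. The 13 mitochondrially encoded genes, which code for subunits of the same complexes, were lower in 13 of 13 by group mean. In 6 of them both Yy1 knockdown libraries were below both controls. Of all tested genes, 40.7% had no overlap between groups in either direction. The 13 had a median of -0.18 (camera adjusted p = 0.00708, adjusted p = 0.898 with an estimated correlation). Their estimated correlation was 0.473, against the preset 0.01, so they are not 13 independent measurements. Fits that leave out a library have 1 library in a group and take the spread from the other group alone, so their adjusted p values, here and below, are a rough guide and no call is based on them. The mitochondrially encoded list missed the threshold without control knockdown replicate 1 and without Yy1 knockdown replicate 1. Its mean log2 fold changes there were -0.0911 and -0.126, against -0.186 with all libraries. Control knockdown replicate 1 had 8.97% of fragments from mitochondrial genes, against 6.5 to 6.88% in the others. The ribosomal RNAs mt-Rnr1 and mt-Rnr2, which are not in this list, held 2.11% and 4.24% of its fragments. In the other libraries they held 1.52 to 1.62% and 2.74 to 3.06%. Mitochondrial ribosomal protein genes had 42 of 75 members lower and did not pass (adjusted p = 0.205).

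Cytosolic ribosomal protein transcripts rose as a list, with 70 of 85 members higher and a median log2 fold change of 0.14 (camera adjusted p = 0.00069, adjusted p = 0.821 with an estimated correlation). Rps3 had 113 ± 4.68 FPKM in control and 146 ± 3.12 FPKM in Yy1 knockdown libraries (SD, n = 2 each). The call was lost without Yy1 knockdown replicate 2 (adjusted p = 0.0838). No member passed with limma, over all genes or adjusted over the list alone. Ribosomal protein genes have many near-identical pseudogene copies, and how the authors' counting shared reads among these is not given in the sources used here. Ribosome biogenesis genes were higher in 30 of 40 members (median 0.18, camera adjusted p = 0.0468, adjusted p = 0.898 with an estimated correlation), with Wdr43 at 369 against 473 FPKM and Polr1c, against that direction, at 30.1 against 19.5 FPKM. That call was lost in 3 of the 4 fits that left out a library, without control knockdown replicate 1 or 2 and without Yy1 knockdown replicate 2. The mean log2 fold change, 0.0961 with all libraries, was 0.0818 and 0.11 without control knockdown replicates 1 and 2. It was 0.178 without Yy1 knockdown replicate 1 and 0.0139 without Yy1 knockdown replicate 2. The call was also lost with a pseudocount of 0.1 (camera adjusted p = 0.0508), median-ratio scaling (0.0764) and quantile normalization (0.0843).

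Transcripts typical of the 2-cell stage, when the zygotic genome is activated, were higher as a list, in 21 of 23 members by group mean. The median was 0.43 (camera adjusted p = 0.00196, adjusted p = 0.821 with an estimated correlation). In 8 members both Yy1 knockdown libraries were above both controls, and in 1 both were below. Of all tested genes 40.7% had no overlap between groups, against 33.3% by chance, so such separation is not particular to this list. No member passed with limma, over all genes or adjusted over the list alone. Tcstv3 had 2.66 ± 0.67 against 7.56 ± 2.08 FPKM and Tdpoz3 5.87 ± 2.69 against 13.03 ± 0.0145 FPKM (SD, n = 2 each). Many of these genes are near-identical copies, so single members are uncertain. The median over members, set against the control mean, was 0.635 in Yy1 knockdown replicate 1 and 0.2 in replicate 2, and the call was lost without replicate 1 of that group (mean log2 fold change 0.273 against 0.441 with all libraries, adjusted p = 0.132) and with a filter of 5 FPKM (adjusted p = 0.0706). Without control knockdown replicate 1 the mean was 0.294 (adjusted p = 0.049). Oocyte transcripts were higher in 25 of 38 members and did not pass (adjusted p = 0.171), and their direction was set by Yy1 knockdown replicate 1. Their mean log2 fold change was 0.423 without Yy1 knockdown replicate 2, where the adjusted p of 0.000107 rests on 1 knockdown library and is not taken as a call, and -0.097 without replicate 1 of that group. Among these, Rnf114 had 13.9 FPKM in control and 7.92 FPKM in Yy1 knockdown libraries, and Npm2 17.9 and 23.5 FPKM.

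Among chromatin regulators, BAF (SWI/SNF) remodeling complex transcripts were lower in 11 of 17 members (median -0.11, camera adjusted p = 0.0429, adjusted p = 0.821 with an estimated correlation), with Smarcd3 at 3.39 against 1.08 FPKM and Arid2 at 11.7 against 8.41 FPKM. The estimated correlation of this list, -0.0401, was also below the preset 0.01. The correlation used in that setting is thus argued against as the reason for that loss, though its estimate is imprecise too. The call was lost without control knockdown replicate 1 or 2 and without Yy1 knockdown replicate 1. It was also lost with a filter of 5 FPKM (camera adjusted p = 0.128) and with quantile normalization (0.0593). The mean log2 fold change, -0.17 with all libraries, was -0.188, -0.151 and -0.162 in those leave-one-out fits. With the 5 FPKM filter it was -0.132 and with quantile normalization -0.174. INO80 complex genes, partners of YY1 in a remodeling complex, were divided evenly, 7 higher and 7 lower (adjusted p = 0.643). Of 31 other chromatin remodelers, chaperones and repressors 1, Baz1a, passed adjusted over the list alone, and the list did not (adjusted p = 0.925). Replication-dependent histone transcripts were lower in 46 of 61 members (median -0.15, camera adjusted p = 0.0208, adjusted p = 0.898 with an estimated correlation), but without control knockdown replicate 1 the list was higher (mean log2 fold change 0.148, adjusted p = 0.049), so that library sets its direction. Without Yy1 knockdown replicate 2 it did not pass (adjusted p = 0.322).

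Lineage and stress lists did not pass with all libraries. Trophectoderm genes were higher in 11 of 16 members (adjusted p = 0.244), with Krt18 at 8.12 ± 5.08 against 24.7 ± 5.53 FPKM. Inner cell mass and pluripotency genes were lower in 16 of 26 (adjusted p = 0.125), and of these Zfp42 alone passed adjusted over the list alone. The mean log2 fold change of the list was -0.172 with all libraries. It was -0.125 and -0.22 without control knockdown replicates 1 and 2, and -0.263 and -0.082 without Yy1 knockdown replicates 1 and 2. Such fits, with 1 library in a group, are not taken as calls. Klf4 had 28.9 against 19.3 FPKM and Tdh 11.3 against 18.3 FPKM. Primitive endoderm genes had 7 measured members (adjusted p = 0.618), and compaction, polarity and Hippo genes 29 (adjusted p = 0.752), with Cyr61 at 3.72 against 8.74 FPKM. Targets of p53 had 3 of 22 members pass adjusted over the list alone, all lower, namely Ccng1, Pmaip1 at 5.37 against 2.26 FPKM and Trp53inp1 at 10.2 against 5.71 FPKM, while the list did not pass (adjusted p = 0.618), its median being above 0 and its mean below. Proteasome genes were lower in 20 of 32 members and did not pass (adjusted p = 0.0634), with Psmc6 at 79.3 against 42.8 FPKM and Psmc3 at 46.9 against 20.1 FPKM passing adjusted over the list alone. The proteasome list passed with no filter (0.0289), median-ratio scaling (0.0489) and voom (0.0426). The mean log2 fold change of the proteasome list was -0.136 with all libraries. It was -0.192 and -0.0786 without control knockdown replicates 1 and 2, and -0.102 and -0.169 without Yy1 knockdown replicates 1 and 2. Of 34 replication and division genes, Kif11 (47.0 against 28.6 FPKM) and Mcm5 (25.7 against 14.6 FPKM) passed adjusted over the list alone, and the list did not (adjusted p = 0.925). Glycolysis (adjusted p = 0.925), cholesterol synthesis (0.962), the integrated stress response (0.925), heat shock (0.891) and the interferon response (0.643, 5 of 29 members measured) did not pass either. In glycolysis Hk2 passed adjusted over the list alone.

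Most markers of other cells were below the filter. Of 18 cumulus and granulosa cell markers 1, Amhr2, exceeded the filter, at 5.05 ± 0.434 against 7.55 ± 0.356 FPKM. As the 1 member tested it passed adjusted over the list alone, higher, with both knockdown libraries above both controls. The markers of this list summed to 6.32 and 5.72 FPKM in the control and 9.37 and 8.89 FPKM in the Yy1 knockdown libraries. Most of these sums is Amhr2 itself, the median of the marker means being 0.0132 FPKM. The cause was not tested. Of 15 sperm markers 1, Odf2, exceeded it, at 3.46 against 3.79 FPKM, and of 10 blood cell markers 0, the highest being Hba-a2 at 0.572 FPKM. Some rows vary widely between libraries of a group, such as Gm26917 at 643 and 3902 FPKM in the control libraries.

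**Figure D2:**
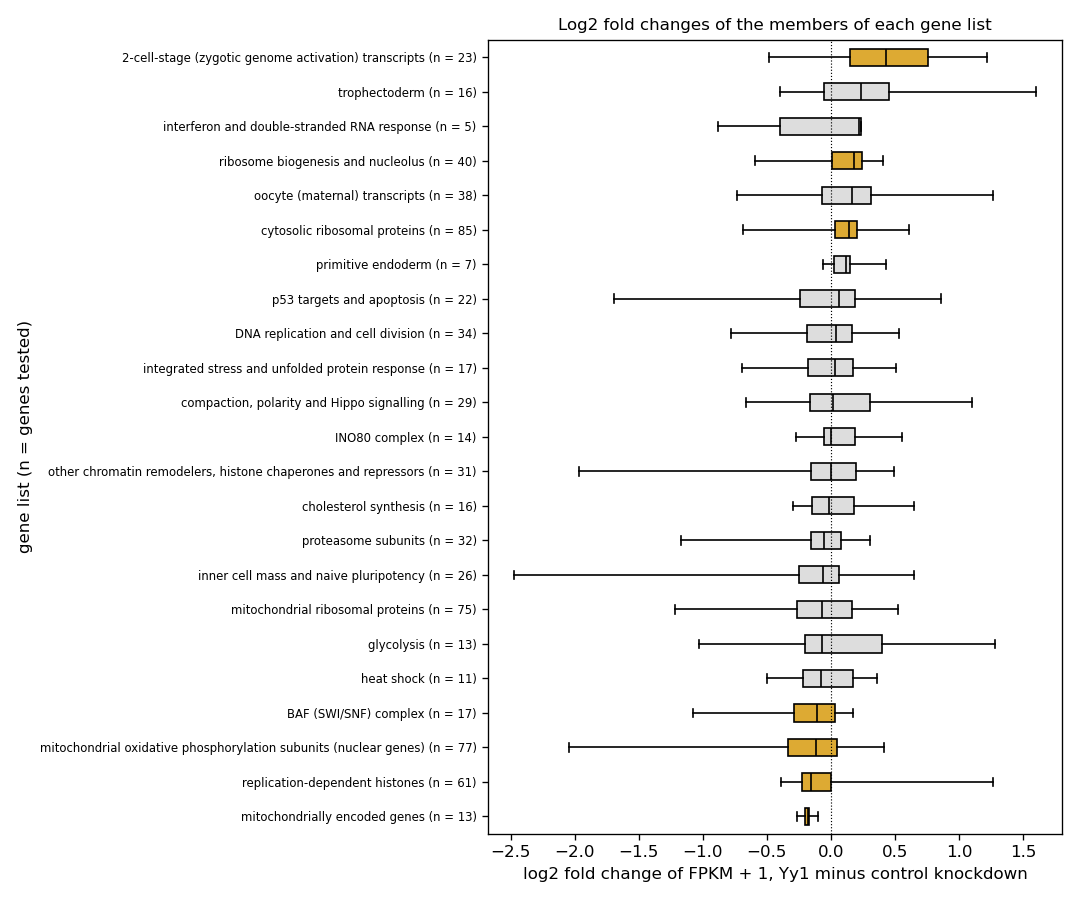
Log2 fold changes, Yy1 knockdown minus control knockdown, of the members of the 23 tested gene lists; each box spans the quartiles, the line inside is the median and the whiskers reach the extremes. Yellow boxes mark the 7 lists with a camera adjusted p under 0.05, 3 higher and 4 lower; with an estimated correlation 0 of these passed.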

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

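The protein-coding and voom settings were chosen after seeing the data. The count of called genes was 0 with the pseudocount, scaling, no-filter, no-trend and leave-one-out alternatives, and with an added fold threshold. It was 4 with a filter of 5 FPKM (1 higher, 3 lower, fewer genes tested; Yy1, Zfp42, Baz1a and Gm13230, the last named after its values were seen), 1 with robust eBayes (Yy1), 3 at an adjusted p of 0.1, 14 among protein-coding genes (2 higher, 12 lower) and 13 with voom (2 higher, 11 lower). The cause of the robust and voom differences was not tested. Yy1 was lower under all alternatives run, with log2 fold changes from -3.07 to -3.45 and adjusted p from 5.5e-05 to 0.809. It passed at -3.26 with the 5 FPKM filter (0.0108), robust eBayes (0.0496) and protein-coding genes (0.000493), and at -3.45 with voom.

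The 7 called lists became 0 with an estimated correlation and 0 with fry, where the cause was not tested beyond the correlations given above, and 4 with protein-coding genes (3 higher, 1 lower). In that setting the histone and mitochondrially encoded lists could not be tested, as no symbol of theirs matched a RefSeq biotype, and BAF missed the threshold (adjusted p = 0.116). Leave-one-out fits have 1 library in a group, so their spread comes from the other group alone and their p values are a rough guide. In these 5 to 6 lists passed, of which 3 to 5 were among the 7 with their direction, and in settings besides these 5 to 8, of which 5 to 7 were. With the replicate block, 0 genes and 6 lists were called, Yy1 stayed at -3.26 (adjusted p = 0.379) and BAF missed the threshold (adjusted p = 0.0511). Deviations of same-numbered libraries correlated at 0.0994, and the labels do not say that numbers pair libraries. Among the named genes and tested lists these crossed 0 on leaving out a library, and the cause was not tested. Mean log2 fold changes ranged from -0.293 to 0.148 for histones, -0.097 to 0.423 for oocyte transcripts, -0.0847 to 0.0257 for other chromatin remodelers, -0.0587 to 0.0938 for cholesterol synthesis, -0.0687 to 0.0548 for the integrated stress response, -0.00772 to 0.128 for INO80 (whose test direction did not turn), -0.189 to 0.124 for heat shock, -0.344 to 0.105 for the interferon response and -0.0159 to 0.00856 for DNA replication. Log2 fold changes ranged for Lamb1 from -0.015 to 0.345, Lamc1 from -0.015 to 0.247 and Fgfr2 from -0.183 to 0.351. The direction of the test, not always that of the mean, also turned for 5 lists far from the threshold: other chromatin remodelers (-0.0295 with protein-coding genes and with ranks), glycolysis (0.0384 with the replicate block and with ranks), cholesterol synthesis (-0.00551 with quantile normalization, 0.0176 with ranks), DNA replication (-0.00366 with protein-coding genes and with ranks) and the integrated stress response (0.0179 with no filter, -0.00692 with protein-coding genes and with fry, -0.00999 with voom). Of 271 alternative values of the 16 lists not called, 239 kept direction and side, 8 passed (proteasome, oocyte and inner cell mass lists, 5 of the 8 in leave-one-out fits) and 24 turned. For the 7 lists, 83 of 117 alternative values kept the call, 33 missed the threshold and 1 reversed; the 2-cell list missed it with the 5 FPKM filter (adjusted p = 0.0706). Among the 19 ranked genes besides Yy1, 240 of 259 alternative values kept direction and side of the threshold and 19 came to pass it. With 29302489 to 34429515 fragments per library, depth limits mainly rows with few fragments, such as Platr16 with 2 in a library.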

Other observations

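The tests of slower development and of the siRNA, and the rows named here for single genes, were chosen after the values were seen. Gm13230, a predicted gene outside the naming rule, had 5.81 and 3.62 FPKM in the control libraries and 42.3 and 44.0 FPKM after Yy1 knockdown (limma adjusted p = 0.0928). Pnrc2 and Ndufaf6, an assembly factor of respiratory complex I, were among the protein-coding genes called lower when those were tested alone, with log2 fold changes of -2.03 and -1.76. Pnrc2 was also called with voom and Ndufaf6 was not. The Y-linked gene Ddx3y had 4.6 and 2.13 FPKM in control and 0.282 and 0.873 FPKM in Yy1 knockdown libraries. Y-linked Eif2s3y had 1.66 and 1.09 against 0.903 and 2.08 FPKM, so these Y-linked genes, both at low levels, did not move together. X-linked Xist had 7.12 and 25.5 FPKM in control and 15.8 and 17.9 FPKM in Yy1 knockdown libraries. Whether the sex of the embryos differed between libraries was not tested.

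The first pattern is the lower level of nuclear oxidative phosphorylation transcripts. Gene length and expression level are argued against, since the list median (-0.12) lay at percentile 0.44 of 10000 random protein-coding lists matched on both. Reads shared with pseudogenes stay open: members with no named pseudogene row kept a camera p of 3.97e-05, but these were 72 of 77, so the test could hardly come out otherwise. A lower level of mitochondrial protein transcripts in general cannot be told apart from a change of these subunits, as 62 import, assembly and citric acid cycle genes had a median of -0.04 (95% bootstrap bounds -0.146 and 0.0854, a camera p of 0.119). With 1 siRNA against Yy1 among the RNA libraries, an effect of the one siRNA apart from Yy1 may account for any of these differences, and loss of YY1 itself remains the untested biological explanation.

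The second pattern is the higher level of 2-cell-stage transcripts. With each family of near-identical copies summed, 10 rows were left, of which 9 were higher. The camera p was 0.024 (p = 0.143 with an estimated correlation). Under the preset correlation only, this argues against shared reads among copies as the whole cause. Both knockdown libraries stood above both controls for Sp110, Tcstv, Tdpoz and Usp17l. The groups overlapped for Zscan4 (1.945 and 10.96 against 15.69 and 7.815 FPKM), Zfp352 (4.071 and 1.329 against 3.675 and 9.296 FPKM), Arg2, Eif1a and Obox. The median fell from 0.432 to 0.24 with the summing, so shared copies may account for part. Slower development of the knockdown embryos could raise such transcripts and would lower trophectoderm genes, but that list was higher in 11 of 16 members without passing (adjusted p = 0.244), and the oocyte list, also higher, did not pass either (adjusted p = 0.171), so this stays open. In Yy1 knockdown replicates 1 and 2 the medians were 0.393 and -0.03 for oocyte and 0.423 and -0.0692 for trophectoderm genes. The mean log2 fold change of the 2-cell list, 0.441 with all libraries, was 0.273 without Yy1 knockdown replicate 1 and 0.294 without control knockdown replicate 1.

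The third pattern is that 14 genes passed when protein-coding genes were tested alone and 0 when all rows were. At matched expression the other rows had a median residual SD 1.68 times that of protein-coding genes (1.19 to 2.31 over 50 bins). Of the other rows 1474 have no RefSeq match and can include coding genes under older symbols. Moderation gave the spread shared across genes 3.53 prior degrees of freedom over all rows and 6.13 with protein-coding genes alone. From the first fit to the second, standard errors of called genes fell for some (0.284 to 0.237 for Ndufaf6) and rose for others (0.165 to 0.173 for Hk2). The weaker test over all rows thus went with the fewer prior degrees of freedom, not with larger standard errors throughout. Whether the larger spread of the other rows lowered them was not tested. Fewer genes in the adjustment for multiple tests is argued against as the whole cause, since the p-values of the fit over all genes, adjusted over protein-coding genes alone, gave 1 call. No biological explanation was tested for this pattern.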
